A study of Homo sapiens with 8 samples.

How the data were processed

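Chromatin accessibility was measured by ATAC-seq (assay for transposase-accessible chromatin, in which the Tn5 transposase cuts and tags open DNA) in 8 libraries of BJ cells, an established strain of human dermal fibroblasts. Per the labels' protocols, nuclei were tagmented with Tn5. The deposited file of each library is a list of peaks. Bowtie2 and MACS2 are named in the submitters' processing notes as the tools used, and hg19 (GRCh37) as the genome build; versions, parameters, read filters, duplicate handling and any shift of reads for the Tn5 offset are not given in the sources used here. Each list has 9 columns in the layout of a MACS2 broad peak file and holds the peaks of a single library, so replicates were not pooled before deposit.

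For each peak the authors deposited a score, a fold enrichment over the caller's background, a −log10 p-value and a −log10 q-value. The deposited score lay within 1 of 10 times the −log10 q-value in every list. Every deposited peak had a −log10 q-value of at least 1. The lists carry no read counts, so the sequencing depth is unknown. The strength of a list is described below by its number of peaks and its q-values. These per-peak values are the authors' own, and they were used only to describe and to rank peaks within a list.

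Samples were grouped by their titles into control, p63, p63+KLF4 and mutant p63+KLF4, with 2 libraries each. The labels number the replicates but do not say that they came from separate cultures; the series' design text calls them biological duplicates. Within each list peaks were ranked by −log10 q, then −log10 p, then fold. The 50000 highest-ranked peaks of the 8 lists were merged where they overlapped by at least 1 bp, which gave 146850 regions. A region was called present in a library when a peak among its 50000 highest-ranked overlapped it by at least 1 bp. It was called absent when no peak of the whole deposited list overlapped it. A region was gained in a comparison when present in both libraries of the first group and absent from both of the second, and lost in the reverse case. These rules, the comparisons and the alternatives were fixed before the data were examined, except where stated.

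With 2 libraries against 2, the smallest two-sided p-value of an exact permutation test is 0.333, so no p-value is given for a count of regions. Each count is set beside the counts from the other splits of the same 4 libraries, which mix the groups. Agreement between libraries was tested by an exact permutation test over the 105 ways to pair 8 libraries. Shares of regions have Wilson 95% intervals, which cover counting error only, since regions are not replicates. The named regions are the 5 gained and the 5 lost regions of each comparison with the best mean percentile rank in the 2 libraries that hold them, a rule fixed in advance. In the closing section, 1 Mb windows with at least 5 regions were tested for clustered changes with a hypergeometric test and Benjamini-Hochberg adjustment. This test was added after the data had been seen, as were the comparisons of region classes matched on rank in the closing section and the baseline shares of peaks per library. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

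The calls were tested on simulated lists of 146850 regions with 100 planted gains of each of 2 sizes, using each group's own replicate correlation. That correlation was estimated from peaks of any rank, whereas presence uses highly ranked peaks. The simulated noise in presence may therefore be too small and the unplanted gains too few. An earlier version applied the controls' correlation to every group; it was replaced after its outcome had been seen, because it understated the noise of the mutant libraries. For p63 against control, 80% of planted gains of 3 SD and 100% of those of 5 SD were recovered, with 0 gained regions that had not been planted. For p63+KLF4 against control, 78% and 100% were recovered with 5 unplanted regions. For p63+KLF4 against p63, the shares were 84% and 100% with 0 unplanted regions. For mutant p63+KLF4 against control, 60% and 99% were recovered with 105 unplanted regions. For mutant p63+KLF4 against p63+KLF4, 56% and 95% were recovered with 28 unplanted regions. Gains were planted only in regions with a low underlying signal, where control peaks were rare. The recovered shares therefore do not cover gains at regions with a weak control peak, which the rule cannot call. Apart from the planted gains, simulated groups differed by list length and replicate noise only.

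No genome or gene annotation of the hg19 build was used here, and coordinates were not converted from another build. Regions are therefore named by their hg19 coordinates, counted from 1. The gene list tests, the motif tests and the check of the exons of the expressed factors that had been planned were not run. The alternatives tried were other numbers of ranked peaks for presence and absence, a stricter overlap, autosomes alone, and leaving out each library. Added after the data had been seen were the counts from the p63+KLF4 and control lists with the same day in their peak names, and the overlap of gains with a different control library for each factor group. The regions present in each treated list alone and absent from both controls are the planned counts without the other replicate; setting them side by side was chosen after the data had been seen.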

Results

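The accessibility of chromatin was profiled in BJ fibroblasts after ectopic expression of p63, with or without KLF4, for 72 hours according to the series' design text. p63 is a transcription factor of the p53 family that is required for stratified epithelia, and KLF4 is a zinc-finger factor with a role in epidermal differentiation. The combination has been used to convert fibroblasts towards keratinocyte-like cells. There were 4 groups of 2 libraries: an empty-vector control, wild-type p63, wild-type p63 with KLF4 (p63+KLF4), and p63 carrying the I537T substitution in its SAM (sterile alpha motif) domain with KLF4 (mutant p63+KLF4). The 2 control lists held 242982 and 204743 peaks covering 86.6 and 67.9 Mb. The p63 lists held 281409 and 223982 peaks, and the p63+KLF4 lists 234571 and 258661. The second mutant list, with 262434 peaks over 85.1 Mb and a median −log10 q of 3.59, was comparable in length to these. The first mutant list was the shortest, with 137611 peaks over 22.6 Mb and a median −log10 q of 1.29. Its 50000th peak had a −log10 q of 1.43, against 3.35 to 8.08 in the other lists.

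The peak names inside the lists do not all match the labels. The names carry 6 days in control replicate 1 and p63+KLF4 replicate 2, and 3 days in control replicate 2 and p63+KLF4 replicate 1. The names in control replicate 1 carry "RTTA". The names in control replicate 2 share the word "Both" with the p63+KLF4 lists but lack their "Dox". Neither control list names an empty vector, and the names leave open whether the controls came from the same line. The names in the p63 lists carry neither a day nor "Dox", and those in the mutant lists give I537T and "Dox" without a day. KLF4 is named in none of the 8 lists. Groups follow the labels throughout.

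Libraries of the control, p63 and p63+KLF4 groups shared more accessible regions with their own replicate than with libraries of the other groups in this set. The mutant group was the exception: its second library shared more with the controls than with its own replicate. The 2 control libraries shared 70.9% of their 50000 highest-ranked peaks, the p63 libraries 73.0% and the p63+KLF4 libraries 61.7%. Between groups, control and p63 libraries shared 57.0% on average (range 56.3 to 57.4 over 4 pairs) and control and p63+KLF4 libraries 45.1% (41.2 to 49.1). The p63 and p63+KLF4 libraries shared 49.8% (47.6 to 51.9). Mutant replicate 2 shared 68.0% and 66.8% with the controls, 56.2% and 50.6% with the p63+KLF4 libraries, and 56.0% and 55.9% with the p63 libraries. Mutant replicate 1 shared 25.8 to 31.6% with libraries of the other groups and 33.0% with mutant replicate 2. Same-group pairs shared 59.6% on average and other pairs 47.1%, a difference of 12.6 percentage points (exact permutation test over 105 pairings, one-sided p = 0.00952, the smallest possible).

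**Figure D1:**
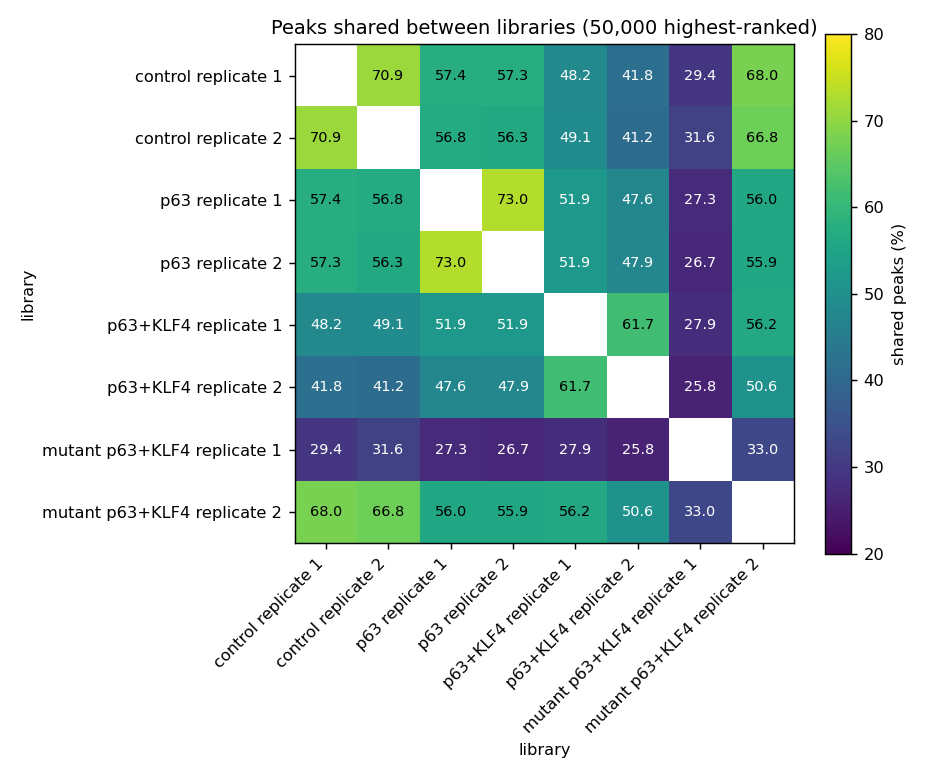
Percentage of the 50000 highest-ranked peaks shared between each of the 28 pairs of libraries (rows and columns, colour scale in percent, mean of both directions). The control pair (70.9%) and the p63 pair (73.0%) are the most similar, mutant replicate 2 shares 66.8 and 68.0% with the controls, and mutant replicate 1 shares at most 33.0% with any library.

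The comparison of p63 with control asks what wild-type p63 alone changes in fibroblast chromatin. Expression of p63 was accompanied by 4015 gained regions and 472 lost regions. The gained regions had a median width of 412 bp and the lost regions of 363 bp, against 348 bp for all 146850 merged regions. Regions present in all 8 libraries had a median of 970.5 bp. Merging the peaks of several lists widens a region, so no trait of the gains is read from these widths. The best-ranked gained region lay on chromosome 5 from 146795159 to 146795592, with a fold enrichment of 8.99 and 8.75 in the p63 libraries and no peak in either control. It was followed by regions on chromosome 7 from 20602069 to 20602516 (fold 9.70 and 9.33), chromosome 9 from 13295583 to 13295949 (10.3 and 9.62), chromosome 10 from 96386266 to 96386687 (8.18 and 9.33) and chromosome 7 from 19979354 to 19979763 (9.03 and 9.36). The regions on chromosomes 5, 9 and 10 also had peaks in both p63+KLF4 libraries, and the 2 regions on chromosome 7 had no peak in any library outside the p63 group. The lost regions were weaker in rank, with a median percentile of 13.7 in the controls against 9.46 for gained regions in the p63 libraries. The best-ranked lost region, on chromosome 5 from 297096 to 297483, had a fold enrichment of 8.43 and 6.10 in the controls and again had peaks in both p63+KLF4 libraries. The next were on chromosome 12 from 125626742 to 125627514 (6.01 and 4.91), chromosome 3 from 19743740 to 19744914 (5.39 and 6.01), chromosome 18 from 38926898 to 38927543 (7.54 and 6.59) and chromosome 7 from 136989239 to 136990199 (6.57 and 6.66). All 5 had peaks in both p63+KLF4 libraries and in mutant replicate 2. The splits that mix p63 and control libraries gave at most 9 regions in a direction. The share of gained regions among the changed ones, 89.5%, depended on the rules: it was 57.8% with the 50000 highest-ranked peaks used for presence and absence alike (10283 gained and 7499 lost regions), 68.8% with any deposited peak counted as presence and 69.8% without control replicate 2. With presence or absence required in a single library of a group, the gains were 7059 without p63 replicate 1, 6675 without p63 replicate 2 and 6440 without control replicate 1, and the losses 1081, 823 and 1696, with 1913 without control replicate 2.

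The comparison of p63+KLF4 with control asks what the factor combination changes. With p63 and KLF4 expressed together, 6293 regions were gained and 679 lost. The best-ranked gained region lay on chromosome 4 from 175255694 to 175256491, with a fold enrichment of 9.32 and 9.82 in p63+KLF4 and of 8.83 and 7.99 in p63. The next were on chromosome 4 from 155641337 to 155641665 (8.82 and 10.4), chromosome 2 from 214616135 to 214616586 (8.61 and 10.7), chromosome 2 from 168953857 to 168954287 (7.48 and 9.41) and chromosome 4 from 112370890 to 112371207 (8.94 and 10.96). All 5 had a peak in both p63 libraries and in mutant replicate 2, where the region on chromosome 4 at 155641337 reached a fold of 8.06 and the other 4 lay between 3.05 and 5.01. The best-ranked lost regions were on chromosome 4 from 106887090 to 106887544 (7.29 and 6.67 in the controls), chromosome 6 from 9467987 to 9468386 (7.45 and 6.73), chromosome 2 from 71698514 to 71698735 (6.35 and 5.23), chromosome 4 from 87247647 to 87247930 (7.32 and 6.48) and chromosome 8 from 130896109 to 130896361 (6.81 and 5.29). All 5 kept a peak in both p63 libraries and in mutant replicate 2. Mixed splits gave at most 46 regions. With the 50000 highest-ranked peaks for presence and absence alike, 12382 regions were gained and 11414 lost, and the gained share fell from 90.3% to 52.0%. Within the lists named for 3 days the counts were 14422 gained and 6290 lost, and within those named for 6 days 16579 and 4573, each from a single library per group and chosen after the data had been seen. Without p63+KLF4 replicate 1 or 2 the gains were 15328 and 10547, and the losses 1388 and 2571; without control replicate 1 or 2 the losses were 2407 and 2944.

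**Figure D2:**
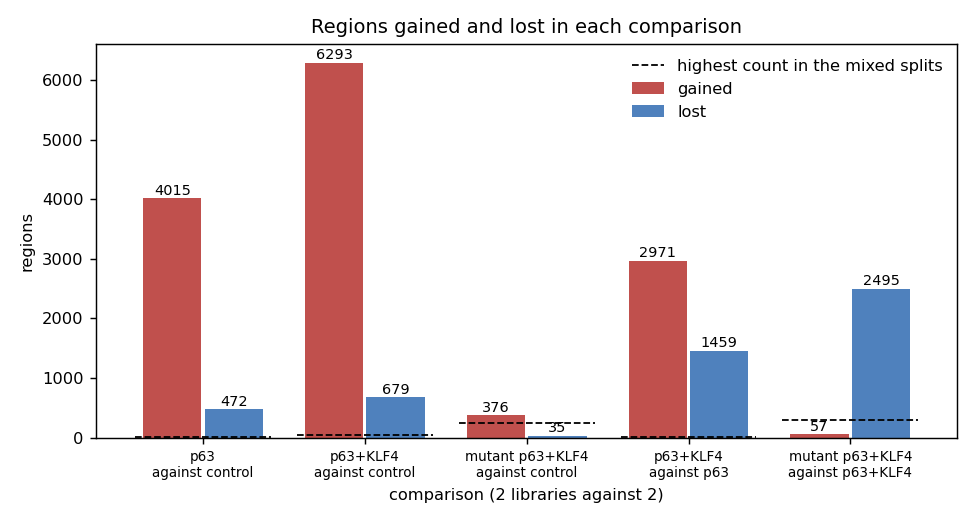
Number of regions gained (red) and lost (blue) in each comparison of 2 libraries against 2; the dashed line is the highest count in the splits that mix the groups. The 4015 and 6293 regions gained with p63 and p63+KLF4 lie far above their mixed splits (9 and 46), and the 376 gained with mutant p63+KLF4 lie near theirs (241).

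The regions gained with p63 and with p63+KLF4 overlapped in part. Of the 6293 regions gained with p63+KLF4, 1057 (16.8%) were also gained with p63, and 2281 had no peak in either p63 list. Some peak of any rank was found in both p63 libraries for 47.9% of the 6293 regions (95% interval 46.7 to 49.1, counting error only), for 16.8% when only highly ranked peaks counted, and for 63.8% in at least 1 p63 library. Of the 4015 regions gained with p63, 65.5% and 77.3% had a peak in the p63+KLF4 libraries, and 744 had none in either. Independent lists of these lengths would share 172 of the 146850 regions, or 544 of the 46467 regions absent from both controls. Of those 46467 regions, 25905 were present in a p63 or p63+KLF4 library, and the others in a mutant library only. Only the 25905 could be gained with either factor group. The number expected over them is well above 544 and nearer to the 1057 found. The 172 and 544 therefore overstate the excess, and no clear excess is read from them. Unchanged groups simulated against the same controls gave 0.44 and 4.68 gained regions on average and shared 0.03, over 100 simulations. All simulated libraries had a common underlying signal and differed by list length and replicate noise only. The simulation therefore cannot say how many gains a difference between groups other than the factors would give. Its noise was estimated from peaks of any rank, so its counts of gained regions may be too low. Setting p63 against 1 control library and p63+KLF4 against the other, tried after the data had been seen, leaves the 1057 regions as they are by definition, since such a region must still be absent from both controls. Independent lists would then share 255 or 306 of all regions, depending on which control goes with which group. The split therefore cannot separate the controls' contribution, and part or all of any excess may come from the shared control libraries.

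In p63+KLF4 against p63, which asks what KLF4 adds, 2971 regions were gained and 1459 lost. The peak names of the p63+KLF4 lists carry "Both", "Dox" and a day, and those of the p63 lists carry none of these. Differences behind these names cannot be told from an effect of KLF4. The best-ranked gained regions were on chromosome 11 from 15805103 to 15805682 (fold 7.63 and 9.83 in p63+KLF4), chromosome 3 from 113085461 to 113086157 (8.51 and 8.82), chromosome 2 from 158135775 to 158136622 (7.88 and 8.63), chromosome 7 from 33571354 to 33572255 (7.97 and 9.51) and chromosome 7 from 141345801 to 141346323 (7.13 and 8.58). The first 4 of these also had a peak in mutant replicate 2, at folds of 6.08, 5.57, 10.2 and 7.57, and the last had none. Across the 2971 gained regions, 72.2% had a peak in mutant replicate 2, and 18.0% and 13.1% had a peak in the controls. The 72.2% was close to the library's 73.7% of all merged regions, many of which have control peaks. It was above its 42.3% of the 25905 regions absent from both controls and present in a p63 or p63+KLF4 library. The comparison thus depends on the baseline. The best-ranked regions lost on adding KLF4 were on chromosome 2 from 155834615 to 155835056 (9.11 and 9.13 in p63), the 2 chromosome 7 regions at 20602069 and 19979354 named above, chromosome 6 from 119711435 to 119711897 (10.1 and 9.06) and chromosome 10 from 84048154 to 84048951 (7.59 and 7.83). The chromosome 6 region, like the 2 on chromosome 7, had a peak in the p63 libraries alone. Of the 1459 lost regions, 34.2% had a peak in mutant replicate 2, and 45.9% and 25.6% had a peak in the controls. Mixed splits gave at most 11 regions. The excess of gained over lost regions did not hold under every rule: the gained share was 67.1%, and 46.9% with the 50000 highest-ranked peaks for presence and absence alike (9594 gained, 10859 lost). The gains were 8478 and 6185 without p63+KLF4 replicate 1 or 2, and the losses 3520 without p63+KLF4 replicate 2 and 3346 and 3311 without p63 replicate 1 or 2.

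Mutant p63+KLF4 showed few changes against control that both of its libraries shared: 376 regions were gained and 35 lost. The gained regions mostly had a peak with p63+KLF4 as well: 93.6% and 98.1% of them had a peak in the p63+KLF4 libraries, against 36.4% and 32.2% in the p63 libraries. Over all 46467 regions absent from both controls, these shares were 45.8% and 53.3% for p63+KLF4, and 36.6% and 33.3% for p63. The 46467 include regions present in a mutant library alone. Over the 25905 of them present in a p63 or p63+KLF4 library, a set chosen by these same libraries, the p63+KLF4 shares were 74.5% and 86.0%. The p63 shares there were 59.3% and 55.5%, so the comparison depends on the baseline. The best-ranked were on chromosome 10 from 64018634 to 64019176 (fold 5.04 and 9.01 in the mutant libraries, 4.63 and 8.32 in p63+KLF4), chromosome 4 from 122695079 to 122695643 (4.77 and 7.92), chromosome 10 from 97347738 to 97348125 (4.81 and 7.47), chromosome 2 from 158640617 to 158641518 (4.54 and 7.67) and chromosome 6 from 135575650 to 135576160 (4.72 and 5.95). All 5 were present in both p63+KLF4 libraries. The best-ranked lost regions, on chromosome 5 from 94726860 to 94727118, chromosome 16 from 9948393 to 9948802, chromosome 9 from 69268566 to 69268940, chromosome X from 135721669 to 135721829 and chromosome 6 from 119998245 to 119998411, had folds of 5.77 to 7.06 in control replicate 1. Mixed splits gave up to 241 regions, so the 35 losses did not exceed them, nor did the gains when any deposited peak counted as presence (7159 against 34737), the simulation of this comparison made 105 gains that were not planted, and the gained share of 91.5% became 29.7% with the 50000 highest-ranked peaks for presence and absence alike (2334 gained, 5529 lost). The count rests on the weak first list: without it, mutant replicate 2 alone had 2171 regions absent from both controls, against 10547 and 15328 for the p63+KLF4 libraries and 6675 and 7059 for the p63 libraries taken alone. These counts use highly ranked peaks, cut at a −log10 q of 8.08 in mutant replicate 2 and of 3.35 to 5.85 in those lists. With any peak, mutant replicate 2 had 29.3% of the 46467 regions absent from both controls, against 45.8% and 53.3% for p63+KLF4 and 36.6% and 33.3% for p63. Without mutant replicate 2 the count was 20905 with 15764 losses. Without control replicate 1 or 2 the losses were 443 and 549, with 709 gains without control replicate 1.

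The comparison of mutant with wild-type p63, both with KLF4, asks what the I537T substitution changes. Regions of p63+KLF4 were missing from the mutant far more often than the reverse: 2495 were lost and 57 gained. Of the 2495 lost regions, 62.8% and 58.8% had a peak in the libraries with p63 alone, and 9.5% and 5.0% in the controls. Over all merged regions these shares were 72.2% and 69.3% for p63, and 65.9% and 59.1% for the controls. Among the 25905 regions absent from both controls and present in a p63 or p63+KLF4 library, the p63 shares were 59.3% and 55.5%. The p63 shares of the lost regions were thus near or below these baselines. The best-ranked lost region lay on chromosome 6 from 99569719 to 99570062, with folds of 8.66 and 9.50 in p63+KLF4. The others were on chromosome 1 from 215435654 to 215436286 (8.57 and 10.9), chromosome 13 from 77742421 to 77742775 (8.92 and 10.8), chromosome 4 from 121489891 to 121490217 (7.61 and 11.9) and chromosome 9 from 18730658 to 18730965 (8.28 and 10.4). None of these 5 had a peak in either control or mutant list, and the last 4 had peaks in both p63 libraries. Of the 57 gained regions, 91.2% and 93.0% had a peak in the controls. The best-ranked were on chromosome 17 from 36139618 to 36139784, chromosome 4 from 138572234 to 138572583, chromosome 16 from 15111128 to 15111321, chromosome 3 from 170101441 to 170101865 and chromosome 9 from 135930140 to 135931092, with folds of 5.05 to 8.96 in mutant replicate 2 and 4.12 to 5.65 in mutant replicate 1. Mixed splits gave up to 289 regions, above the 57 gains and below the 2495 losses, but when any deposited peak counted as presence the 27154 losses lay below the highest mixed split of 32522, while the gained share of 2.23% became 24.96% with the 50000 highest-ranked peaks for presence and absence alike. The losses rest on mutant replicate 2, since leaving out replicate 1 gave 2643 lost and 873 gained regions, whereas leaving out replicate 2 gave 14784 lost and 19480 gained; without p63+KLF4 replicate 1 or 2 the losses were 8110 and 4821, and the gains 141 and 394.

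Across the wild-type gains, the peaks of mutant replicate 2 lay more often below its 50000 highest-ranked than among them. The −log10 q at that rank was 8.08 in this list and 1.43 to 6.86 in the others, so a peak below it here could be among the highest-ranked of another list, and shares of highly ranked peaks are not on the same scale across lists. Of the 6293 regions gained with p63+KLF4 over control, 63.7% had some peak in mutant replicate 2, but 12.8% had one among its 50000 highest-ranked. The corresponding shares were 58.2% and 21.3% in p63 replicate 1, and 53.4% and 22.2% in p63 replicate 2. Of the 4015 regions gained with p63 alone, 33.9% had some peak in mutant replicate 2 and 2.4% a highly ranked one. In mutant replicate 1 these shares were 16.4% and 6.8% for the p63+KLF4 gains, and 7.0% and 2.5% for the p63 gains. As a baseline, mutant replicate 2 had some peak in 73.7% of all merged regions and mutant replicate 1 in 44.7%, so every one of these mutant shares with some peak lay below it. Among the 25905 regions absent from both controls and present in a p63 or p63+KLF4 library, a set chosen after the data had been seen and holding the gained regions themselves, mutant replicate 2 had some peak in 42.3% and a highly ranked one in 5.48%, and mutant replicate 1 in 9.97% and 3.88%. Against this set, the shares with some peak were higher for the p63+KLF4 gains and lower for the p63 gains in both mutant libraries. Control regions lost with the wild-type factors mostly had a peak in mutant replicate 2, which had a peak in 97.3% of the 679 regions lost with p63+KLF4 and in 97.7% of the 472 lost with p63, against 99.9% of all 35288 regions present in both controls; in mutant replicate 1 the shares were 10.5% and 16.7%, against 55.3%.

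**Figure D3:**
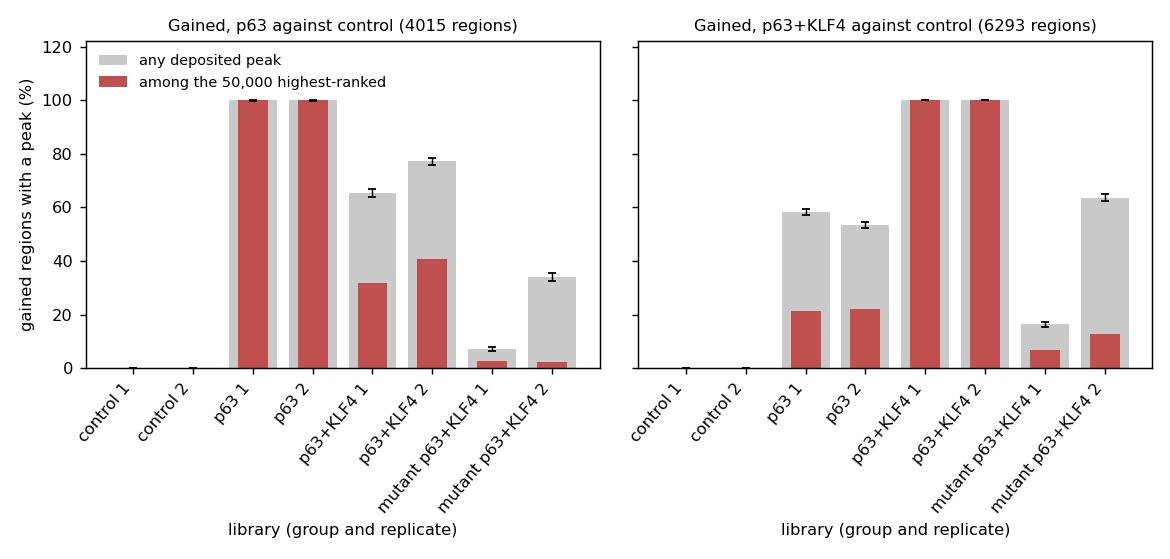
Percentage of the regions gained with p63 (left, 4015) and with p63+KLF4 (right, 6293) over control that have any deposited peak (grey, with Wilson 95% intervals) or one among the 50000 highest-ranked (red) in each library. Values of 0 in the controls and 100 in the defining group follow from the definition; mutant replicate 2 has some peak in 33.9% of the p63 gains and 63.7% of the p63+KLF4 gains.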

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

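The alternatives were planned before the data were examined, except the counts by the day in the peak names and the overlap of gains with a different control library for each factor group, which is fixed by definition at 1057 regions. The direction of each count is kept by definition, so what changes is its size and the balance of gains and losses. Values are given for p63, p63+KLF4 and mutant p63+KLF4 against control, then p63+KLF4 against p63, then mutant p63+KLF4 against p63+KLF4. With any deposited peak counted as presence, 38826, 44356, 7159, 31881 and 4512 regions were gained and 17585, 22887, 10541, 31967 and 27154 lost. With lists of equal length (137611 peaks), 25527, 29594, 5229, 22103 and 5152 were gained and 15990, 23894, 11051, 24522 and 20646 lost. With the 50000 highest-ranked peaks for presence and absence alike, 10283, 12382, 2334, 9594 and 3185 were gained and 7499, 11414, 5529, 10859 and 9575 lost. With 25000 ranked peaks for presence, 1407, 2589, 84, 1044 and 5 were gained and 91, 92, 1, 340 and 865 lost. Requiring an overlap of 50% of the shorter interval moved only the losses of mutant p63+KLF4 against control past 1.5 times, from 35 to 53, and autosomes alone moved none. Leaving out each library gave 4411 to 7059, 6969 to 15328, 462 to 20905, 3643 to 8478 and 141 to 19480 gained, and 823 to 1913, 1388 to 2944, 37 to 15764, 2153 to 3520 and 2643 to 14784 lost, since presence or absence was then needed in 1 library of that group. Between the lists named for 3 and for 6 days, p63+KLF4 gained 14422 and 16579 regions over control and lost 6290 and 4573. The balance reversed in places. The gained share of mutant p63+KLF4 against control, 91.5%, became 40.4% as deposited, 32.1% with equal lists and 29.7% with 50000 peaks throughout, and ranged from 45.7% to 98.3% without each library. That of p63+KLF4 against p63, 67.1%, became 49.9%, 47.4% and 46.9%. That of mutant against wild-type p63+KLF4, 2.23%, ranged from 1.71% to 56.9% without each library, the highest without mutant replicate 2. In the 3 comparisons without mutant libraries, gains and losses exceeded the highest mixed split under these 6 settings. In mutant p63+KLF4 against control the highest mixed split exceeded the gains as deposited (34737), with equal lists (12231) and with 50000 peaks throughout (4216), and the losses in the 6 settings except with 50000 peaks throughout. In mutant against wild-type p63+KLF4 it exceeded the gains in all 6 settings, and the losses as deposited (32522). The share of p63+KLF4 gains with a peak in both p63 libraries, 47.9%, was 16.8% for highly ranked peaks and 63.8% for 1 of the 2 libraries; for the mutant libraries 14.6% became 2.94% and 65.5%. The excess of sharing within groups, 12.6 points, stayed past the threshold with all peaks (7.07 points) and with the stricter overlap (12.6). No paired analysis was possible because the counts of regions come from no test, a region gained in both libraries is the same set however the libraries are paired, and the blocked motif tests were not run. The gene list and motif alternatives were not run. Depth is unknown, and the weak first mutant list limits what its group can show.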

Other observations

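The tests of 1 Mb windows, the comparison of regions with and without p63 peaks, the tests matched on rank and the test of the share of cells responding were chosen after the results had been seen. Few windows passed the adjusted threshold, and only in the comparisons of p63 with control and of p63+KLF4 with p63 among the 5 comparisons. Both of these use the 2 p63 libraries. Among 2393 windows of 1 Mb, 0 held more regions gained with p63 over control than the regions present in p63 would give by chance (exact hypergeometric test, Benjamini-Hochberg adjusted p under 0.05), and 92 had an unadjusted p under 0.05. The same held for p63+KLF4 over control, with 0 of 2134 windows and 80 at an unadjusted p under 0.05. The p63+KLF4 window with the lowest p, on chromosome 3 from 134000001 to 135000000, had 16 gained among 32 present regions where 6.56 were expected (exact hypergeometric test, adjusted p = 0.411). Regions lost with p63 were clustered in 6 windows of 2356, regions gained on adding KLF4 to p63 in 3 of 2134, and regions lost on adding KLF4 in 6 of 2393. The window on chromosome 6 from 165000001 to 166000000 had the lowest p both for losses with p63 and for gains on adding KLF4. For the latter, 8 of 13 present regions were gained (exact hypergeometric test, adjusted p = 0.0134). With the same p63 libraries in both comparisons, these are not 2 separate observations. In the remaining directions of the 5 comparisons, 0 windows passed: 46 and 33 of 2356 had an unadjusted p under 0.05 for regions lost with p63+KLF4 and with the mutant against control, 37 of 1609 for regions gained with the mutant against control, and 49 of 1609 and 78 of 2134 for regions gained and lost with the mutant against p63+KLF4. The window of losses on adding KLF4 with the lowest p, on chromosome 2 from 83000001 to 84000000, had 65 and 40 deposited peaks in the p63 libraries, 12 and 8 in the controls, 13 and 5 in p63+KLF4 and 7 and 12 in the mutant (exact hypergeometric test, adjusted p = 0.00415, 5 of 7 regions lost). In that window the p63 libraries stood apart from all other groups, the controls included, so it is not particular to adding KLF4. In directions with few changed regions, such as the 35 lost with the mutant against control, 0 passing windows does not exclude clustering. The p-values of the window tests treat neighbouring regions as independent.

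Mutant replicate 2 carried p63+KLF4 gains more often than p63 gains: regions gained with p63+KLF4 but with no peak in either p63 list had a peak in mutant replicate 2 in 66.6% of 2281 cases (95% interval 64.6 to 68.5), below the 73.7% of all regions and above the 42.3% of the 25905 regions absent from both controls and present in a p63 or p63+KLF4 library. Regions gained with p63 and without a peak in either p63+KLF4 list had one in 8.74% of 744 (6.91 to 10.98). The 5236 regions gained with p63+KLF4 and not with p63 were set against the 2958 with the opposite pattern. The difference was 38.8 percentage points after matching on percentile rank, and 34.7 to 48.96 in each of 10 bins. The lowest share in a bin was 58.7% for the p63+KLF4 regions, and the highest was 29.0% for the p63 regions. Percentile rank therefore does not account for the difference. Ranks are set within each list. The −log10 q of the 50000th peak was 3.35 and 5.85 in p63+KLF4, and 5.10 and 5.31 in p63. Equal rank is thus not equal strength, and strength stays open. Among the p63+KLF4 gains, regions without p63 peaks recurred 5.10 percentage points more often than those also gained with p63. Recurrence was thus not confined to regions gained with p63. The bounds for this comparison were written after the values had been seen, and a missing peak in a list need not mean closed chromatin. It therefore does not decide whether wild-type p63 alone opens what recurs. A candidate explanation is that KLF4, expressed in both groups according to the labels, opens part of these regions without full p63 function, but a library with KLF4 alone was not analysed here and the p63 lists may also differ in ways the labels do not give.

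The small number of mutant gains has several possible explanations. Counted by highly ranked peaks, the weak first list is not enough: mutant replicate 2 alone had 0.206 times the regions absent from both controls that the lower p63+KLF4 library had. The cut for such peaks was stricter in mutant replicate 2, at a −log10 q of 8.08 against 3.35. With any peak, mutant replicate 2 had 29.3% of the 46467 regions absent from both controls, against 45.8%. The ratio therefore depends on the rule and does not decide. A second mutant library without the expressed factors was examined among regions present in p63+KLF4 and absent from 1 control. There mutant replicate 2 had a peak at least 42.3 percentage points more often than the other control (59.8% against 10.8%, and 63.8% against 21.5%, at 204743 peaks per list). It was therefore unlike a control library in these regions. Absence from 1 control also lowers the share in the other, and the controls lack the "Dox" of the mutant peak names. The test cannot tell the expressed factors from such differences. A smaller share of cells with the full wild-type response stays open: matched on rank in the p63+KLF4 lists, regions without p63 peaks had any peak in mutant replicate 2 8.45 percentage points more often than regions also gained with p63 (2.45 to 25.5 over 10 bins, above 10 in 3) and a highly ranked peak 13.3 points more often (8.43 to 17.1, above 10 in 8), with 5.86 and 3.16 points in replicate 1, and the bounds for this test were written after values had been seen. The I537T substitution itself also stays open, since only 1 informative library carries it.

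On chromosome 6 from 165000001 to 166000000, 8 of 12 regions present in the controls were lost with p63 where 0.161 were expected (exact hypergeometric test, adjusted p = 1.07e-09). The window held 55 and 52 deposited peaks in the controls, 23 and 17 in p63, 53 and 60 in p63+KLF4, and 47 and 53 in the mutant. A single stretch deleted or unmappable in all p63 cells would leave almost no peaks, but the lower p63 list had 32.7% of the lower control list's number in the window, and 31.6% (6 against 19 peaks) between the first and last lost region, from 165459024 to 165645431, where at most 2 neighbouring lost regions had no p63 peak between them. The p63 lists were not shorter in total, with 1.13 times the control lists' peaks genome-wide. Several short deletions, a loss on a single chromosome copy or in part of the cells, and a regional effect of p63 that is not seen with KLF4, could not be told from each other with peak lists.

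The p63+KLF4 libraries, whose peak names carry different days, shared 61.7% of their 50000 highest-ranked peaks, and the one named for 6 days had 15328 regions absent from both controls against 10547 for the one named for 3 days. The controls, whose names also carry both days and differ in "RTTA" and "Both", shared 70.9%.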
